A study of Mus musculus with 16 samples.

How the data were processed

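RNA sequencing was done on RAW264.7 cells, a mouse macrophage line used as an osteoclast precursor. After 12 h of attachment the cells received a phosphate-buffered saline control (PBS), RANKL at 10 ng/mL, vesicles of PC3M cells (EV) at 30 µg/mL, or both, for 48 h or 72 h, per the labels' protocols. This gives 8 groups of 2 libraries and 16 libraries in all. Total RNA was extracted from cell pellets and libraries were made with a TruSeq mRNA kit, per the labels' protocols. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

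Reads were handled with FastQC, HISAT2 and Partek, per the submitters' processing notes. Those notes name the human builds GRCh38 and hg38, while the gene names of the table are mouse symbols. The mouse build, the annotation and the way reads were assigned to genes are not given in the sources used here, so no genome coordinates are printed. Of 20490 genes in the table, 19040 (92.9%) have a name found in the mouse GENCODE M21 annotation, which was used for gene type and length only. In the table, 24 genes carry date-like names. The column of 1 library of vesicles plus RANKL at 48 h lacked the letter for RANKL in its name, and only its group was inferred, from a plus sign that no other group's names hold. It is called replicate 2 of that group because replicate 1 has a column of its own.

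The name of the deposited table speaks of counts, but its values are not whole numbers. The deposited values were taken as log2(RPKM + 1), reads relative to gene length and library size on a log2 scale with 1 added. No source used here states the unit, the base or the added 1, which were found from the values. With base 2, 71.1% of 22509 low values across 3775 genes were within 0.05 of a whole multiple of the unit fitted for the gene and library, at a median distance of 1.1e-05. Base e gave 65.2% with a median distance of 0.0187, and base 10 gave 38.4% with 0.0883. Single-exon genes of known length put the estimated depth at 18.4 M to 20.0 M reads per library (M for mega), with a median of 19.2 M. At that depth 1 read in a transcript of 1 kb is worth 0.0500 to 0.0544 RPKM, and 3 reads are worth 0.150 to 0.163 RPKM. Depth therefore differed little between libraries, and changes of genes below about 1 RPKM rest on few reads.

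The design had planned a count-based test for read counts and limma for other values. Because the values are not counts, limma 3.58.1 in R 4.3.3 was used on the deposited log2(RPKM + 1) values, with a trend of the variance on expression. All 16 libraries entered 1 fit with 8 group means, which shares the estimate of the spread. Genes at 1 RPKM or more in at least 2 libraries were tested, 10365 in number, with Benjamini-Hochberg adjustment and a threshold of 0.05 for each comparison. The levels of this filter and of the naming rule below, planned in CPM, were set in RPKM after the unit of the file was known. Changes on this scale understate those of genes expressed near or below 1 RPKM. Errors of log2 changes are standard errors from limma, and errors of RPKM values are standard deviations of 2 libraries. On simulated data for vesicles against PBS at 48 h with 10365 genes, the fit recovered 30 of 67 genes changed by 0.5 on the log2 scale (44.8%), 63 of 67 changed by 1 (94.0%) and 66 of 66 changed by 2, with 8 false calls.

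Comparisons, gene lists and the rule for named genes were fixed before the data were examined. In each treatment comparison the rule names the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, at 5 RPKM or more in the higher group and without overlap between the libraries of both groups. It also names the 4 members of each list with the smallest adjusted p, and a fixed set of osteoclast and vesicle genes. For interactions and changes over time it takes 5 in each direction, or 5 genes of smallest p where fewer than 5 pass. Predicted genes and pseudogenes are counted but not named. Some genes that the rule names are not reported here.

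The 22 lists hold 426 genes, of which 404 were matched, 4 of them by an older name. They cover osteoclast resorption machinery, osteoclast transcription factors, osteoclast fusion and costimulation, negative regulators of osteoclastogenesis, RANK signalling components, macrophage identity, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, antigen presentation, cell cycle, cholesterol biosynthesis, lipid efflux and LXR targets, oxidative phosphorylation and TCA cycle, glycolysis and hypoxia response, lysosome and V-ATPase, the unfolded protein and integrated stress response, NRF2 targets, immediate early and MAPK feedback genes, TGF-beta and BMP targets, and markers of epithelial or carcinoma cells, of stromal and bone-forming cells and of other blood cells. Lists of at least 5 tested genes were tested with limma's camera, which compares a list with all other tested genes, with a preset correlation of 0.01 and again with the correlation estimated from the data. Sets of RANKL-responsive genes (past the threshold and changed at least 2-fold at 1 time) were tested in the same way in the vesicle comparisons of the other time.

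The alternatives were a median-of-ratios scaling, no filter, a filter above 5 RPKM, the replicate number as a block, only the libraries of the compared groups, and leaving out each library in turn. A group left with 1 library was then assumed to vary like the others. Pseudocounts of 0.1 and 5, the 48 h libraries alone, and a term for 5 libraries that stood apart at 72 h were added after the data were seen. So were the fits without each library for gene lists and for RANKL-responsive sets. The term rests on the difference between the RANKL libraries of 72 h, 1 pair. List tests with the term are given with the preset correlation only, so their p-values may overstate the evidence.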

Results

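Messenger RNA was measured in RAW264.7 cells, which turn into bone-resorbing osteoclasts when they meet RANKL, the ligand of the receptor RANK. The cells had been given extracellular vesicles, small membrane particles released by cells, from PC3M, a metastatic human prostate cancer line, with or without RANKL. Each of the 8 combinations of PBS, vesicles (EV), RANKL and EV+RANKL with 48 h and 72 h had 2 libraries (n = 2 per group throughout). Between 14779 and 15633 genes had a value above 0 in a library, and mitochondrial genes took 19.3% to 26.9% of the summed RPKM. The design asks what vesicles do alone, what they add to RANKL, and how both develop over time.

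Markers of epithelial and stromal cells were low in all libraries, while some listed markers of other blood cells were not. Of 14 listed markers of epithelial or carcinoma cells, 9 were in the table and 0 reached the filter, with Met highest at 0.252 RPKM in any library. Of 12 markers of stromal and bone-forming cells, 8 were in the table and 0 reached the filter, with Runx2 highest at 0.867 RPKM. Of 15 markers of other blood cells, 9 were in the table and 3 were tested. Among these, S100a8, a granulocyte calcium-binding protein, fell with RANKL at 48 h (log2 change -0.99 ± 0.17, limma adjusted p = 0.00146). Itgax, the integrin chain CD11c, rose with RANKL at 72 h (0.89 ± 0.21, adjusted p = 0.0121), a call lost without PBS_72h replicate 1 or RANKL_72h replicate 2. Cd83 reached 14.9 RPKM and Itgax 3.70 RPKM in a library, and Cd83 did not pass in any of the 6 treatment comparisons. S100a8 reached only 1.64 RPKM in a library and had a mean of 0.676 RPKM over the PBS and RANKL libraries of 48 h. Its fall thus rests on low values.

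Libraries separated by RANKL and by time, and 5 libraries of 72 h stood apart. These were RANKL replicate 2, both EV libraries and both EV+RANKL libraries. In 1559 of 10365 tested genes, all 5 lay above (782 genes) or below (777 genes) all 11 others. The most for any other split into 5 and 11 was 546, and libraries that did not differ by group would give 4.75 genes per split. The 5 libraries were picked from these same values. The 4.75 leaves out treatment and time, and the 5 include all vesicle libraries of 72 h. The excess over it therefore does not show a cause beyond treatment and time. Only 22 genes were higher and 15 lower by a gap of at least 0.5 on the log2 scale. Ribosomal protein genes took 10.2% to 10.6% of the summed RPKM in these 5 libraries and 7.56% to 8.99% in the others. The EV against PBS comparison at 72 h lies wholly across this division, and the RANKL libraries of 72 h lie on both sides of it.

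**Figure D1:**
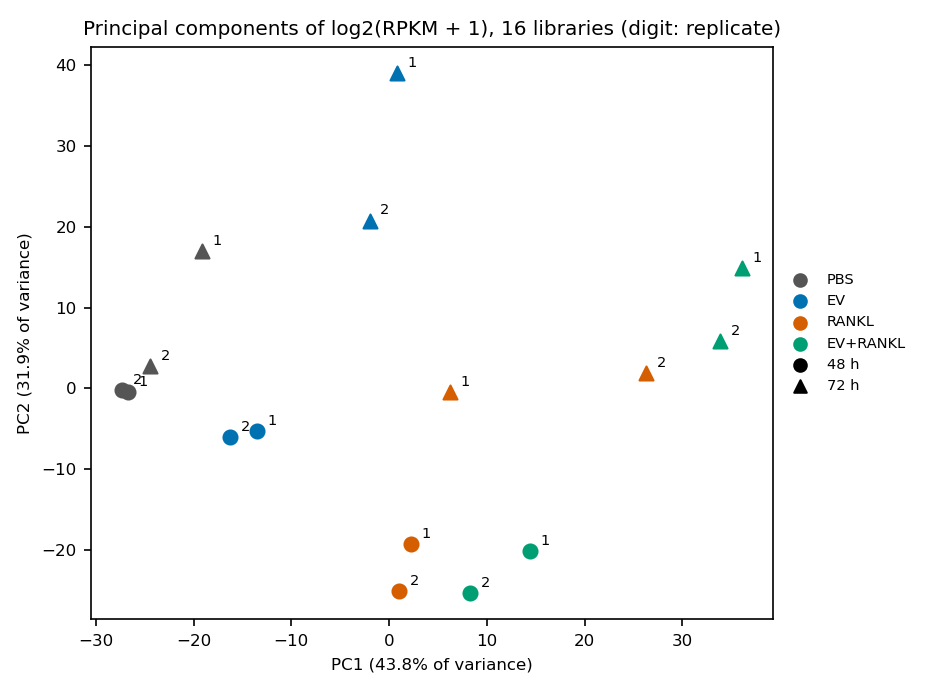
Each point is 1 of 16 libraries on the first principal components of log2(RPKM + 1), which hold 43.8% and 31.9% of the variance; colour gives the treatment, shape the time and the digit the replicate. The RANKL libraries of 72 h lie apart from each other, with replicate 2 nearer to EV+RANKL.

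RANKL alone for 48 h raised a part of the listed osteoclast genes and lowered most of the listed macrophage identity genes. Acp5, the tartrate-resistant acid phosphatase of osteoclasts, was at 86.7 ± 1.80 RPKM against 0.718 ± 0.218 in PBS (log2 change 5.68 ± 0.26, limma adjusted p = 2.0e-07). Atp6v0d2, a proton pump subunit needed for osteoclast fusion, rose by 5.34 ± 0.32, the collagen-degrading protease Ctsk by 2.99 ± 0.49, and Nfatc1, the master transcription factor of osteoclasts, by 2.93 ± 0.17, from 12.0 ± 1.38 to 97.6 ± 5.35 RPKM. Myc (3.25 ± 0.33), Gstt1 (3.26 ± 0.37), Mmp9 (2.73 ± 0.36) and Fosl2 (2.59 ± 0.17) also rose. Igf1, a growth factor made by macrophages, fell from 38.5 ± 1.02 to 1.45 ± 0.648 RPKM (-4.04 ± 0.28, adjusted p = 4.1e-06). Fcgr3 (-2.91), C3ar1 (-2.88), Slc7a8 (-2.81), Tlr13 (-2.77), Dab2 (-2.72), Gpnmb (-2.65) and Ms4a6c (-2.62) fell too. Tnfrsf11a, which encodes RANK, had a log2 change of 0.10 and did not pass, and neither did Dcstamp (0.97), Oscar (0.98), Itgb3 (0.13), Cd9 (0.40), Cd63 (-0.16) or Cd81 (-0.21).

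Among the lists, 10 of 18 osteoclast transcription factors rose and 2 fell with RANKL at 48 h (12 and 2 adjusted over the list alone, camera adjusted p = 4.1e-05, adjusted p = 0.0902 with an estimated correlation). Jdp2 rose by 2.48. Of 18 genes of the resorption machinery, 7 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 7.7e-04, adjusted p = 0.382 with an estimated correlation). Src rose by 1.55. Of 15 macrophage identity genes, 12 fell and 1 rose (13 and 1 adjusted over the list alone, camera adjusted p = 4.4e-12, adjusted p = 0.0720 with an estimated correlation). The Fc receptor Fcgr1 (-2.55) and the scavenger receptor Msr1 (-1.82) fell. Of 22 interferon-stimulated genes, 17 fell (20 lower and 1 higher adjusted over the list alone, camera adjusted p = 4.4e-12, adjusted p = 0.158 with an estimated correlation), such as Parp14 (-1.19) and Dhx58 (-0.94). NRF2 targets, which serve iron storage and antioxidant defence, fell in 11 of 17 members (12 adjusted over the list alone, camera adjusted p = 5.0e-10). Hmox1 (-1.52), Fth1 (-1.18) and Nqo1 (-0.90) were among them. This was the only list whose call held with an estimated correlation (adjusted p = 0.0470). Negative regulators of osteoclastogenesis fell in 8 of 17 members and rose in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 1.0e-04, adjusted p = 0.0902 with an estimated correlation). Irf8 (-1.98) fell. Lysosome and V-ATPase genes fell in 10 of 23 members and rose in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 4.3e-06, adjusted p = 0.300 with an estimated correlation), including the cathepsins Ctsb (-1.98) and Ctss (-1.16).

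Of 18 inflammatory cytokines and NF-kB targets, 6 fell and 1 rose at 48 h with RANKL (9 and 3 adjusted over the list alone, camera adjusted p = 6.6e-04, adjusted p = 0.0720 with an estimated correlation). The chemokine Ccl3 (-1.58) and Il10 (-1.30) fell. The unfolded protein and integrated stress response fell in 6 of 20 members (8 adjusted over the list alone, camera adjusted p = 6.6e-04, adjusted p = 0.158 with an estimated correlation), Atf3 at -2.48 among them. Immediate early and MAPK feedback genes fell in 6 of 14 members and rose in 1 (6 and 2 adjusted over the list alone, camera adjusted p = 0.00461, adjusted p = 0.324 with an estimated correlation), with Egr1 at -1.69. Antigen presentation fell in 3 of 12 members (3 adjusted over the list alone, camera adjusted p = 6.6e-04, adjusted p = 0.0902 with an estimated correlation), including Psmb8 (-0.79). Oxidative phosphorylation and TCA cycle rose in 5 of 22 (7 adjusted over the list alone, camera adjusted p = 4.1e-04, adjusted p = 0.401 with an estimated correlation) and cell cycle in 3 of 27 (3 adjusted over the list alone, camera adjusted p = 0.0172, adjusted p = 0.589 with an estimated correlation). Cholesterol biosynthesis fell in 2 of 22 (0 adjusted over the list alone, camera adjusted p = 1.0e-04, adjusted p = 0.382 with an estimated correlation) and glycolysis and hypoxia response in 1 of 22 (1 adjusted over the list alone, camera adjusted p = 3.2e-04, adjusted p = 0.382 with an estimated correlation). TGF-beta and BMP targets fell in 2 of 8 (3 adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.0902 with an estimated correlation). Osteoclast fusion and costimulation genes fell in 4 of 15 and rose in 1 (5 and 2 adjusted over the list alone, camera adjusted p = 0.0342, adjusted p = 0.382 with an estimated correlation), where the fusion regulator Ocstamp rose by 2.46 and the protease Adam8 fell (-0.78). Lipid efflux and LXR targets (1 higher and 1 lower of 14, camera adjusted p = 0.0504) and RANK signalling components (4 higher of 18, camera adjusted p = 0.547) did not pass as lists. The call of the fusion list was lost without PBS_48h replicate 2 or RANKL_48h replicate 2 (largest adjusted p = 0.0749) and that of the TGF-beta list without PBS_48h replicate 2 (adjusted p = 0.102).

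In all, limma called 1530 of 10365 genes with RANKL at 48 h, 671 higher and 859 lower, of which 82 rose and 227 fell at least 2-fold. The count fell to 856 without PBS_48h replicate 1, 721 without PBS_48h replicate 2, 908 without RANKL_48h replicate 1 and 717 without RANKL_48h replicate 2. All 16 named genes of largest change kept their calls in these 4 fits.

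Vesicles alone for 48 h raised a set of osteoclast genes without RANKL. Acp5 was at 18.3 ± 3.02 RPKM against 0.718 ± 0.218 in PBS (3.49 ± 0.26, limma adjusted p = 2.5e-05), and Atp6v0d2 rose by 3.31 ± 0.32. Nfatc1 rose to 48.2 ± 2.17 RPKM from 12.0 ± 1.38 (1.93 ± 0.17, adjusted p = 9.6e-05), and the AP-1 family members Fosl2 and Jdp2 by 1.69 ± 0.17 and 1.58 ± 0.14. Angptl2, a secreted angiopoietin-like protein, rose from 0.829 ± 0.259 to 6.94 ± 0.828 RPKM (2.12 ± 0.13, adjusted p = 7.6e-06), the protease inhibitor Cst7 by 2.10 ± 0.23 and the gap junction gene Gja1 by 2.10 ± 0.22. Igf1 fell (-1.97 ± 0.28), as did Pram1 (-1.95), Filip1l (-1.48), Slc7a8 (-1.46), the interferon regulator Irf7 (-1.40), Anxa3 (-1.39), Aif1 (-1.37) and Tmem176b (-1.36). Several genes of the mature osteoclast did not pass, with log2 changes of 0.80 for Ctsk, 0.05 for Mmp9, 0.20 for Ocstamp, 0.29 for Oscar and -0.15 for Dcstamp. Tnfrsf11a (-0.03), Irf8 (-0.18), Cd9 (0.29), Cd63 (0.16) and Cd81 (0.08) did not pass either.

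Interferon-stimulated genes moved most as a list with vesicles at 48 h. Of 22 members, 7 fell (16 adjusted over the list alone, median -0.56, camera adjusted p = 1.6e-21, adjusted p = 0.137 with an estimated correlation), among them the antiviral enzyme Oas3 (-1.02), the RNA sensor regulator Dhx58 (-0.73), Ifi44 (-1.26) and Ifi204 (-1.09). Osteoclast transcription factors rose in 4 of 18 members, the named Nfatc1, Jdp2, Fosl2 and Myc (6 adjusted over the list alone, camera adjusted p = 3.7e-04, adjusted p = 0.181 with an estimated correlation), with Myc at 1.53. Resorption machinery rose in 2 of 18 members, Acp5 and Atp6v0d2 (2 adjusted over the list alone, camera adjusted p = 0.0329, adjusted p = 0.671 with an estimated correlation). NRF2 targets fell in 1 of 17, Nqo1 at -1.02 (1 adjusted over the list alone, camera adjusted p = 4.3e-08, adjusted p = 0.0747 with an estimated correlation), and macrophage identity in 1 of 15, Msr1 at -0.61 (3 adjusted over the list alone, camera adjusted p = 4.0e-05, adjusted p = 0.181 with an estimated correlation). With 0 single members past the threshold over all genes, camera placed antigen presentation lower (median -0.30, 5 lower and 1 higher adjusted over the list alone, adjusted p = 5.8e-05, adjusted p = 0.0747 with an estimated correlation). It did the same for negative regulators of osteoclastogenesis (median -0.15, 3 lower adjusted over the list alone, adjusted p = 7.8e-04, adjusted p = 0.181 with an estimated correlation) and lysosome and V-ATPase genes (median -0.18, 1 lower adjusted over the list alone, adjusted p = 9.3e-04, adjusted p = 0.550 with an estimated correlation).

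In vesicles against PBS at 48 h, 5 further lists passed camera, none of them with an estimated correlation or in every fit without 1 library. Cholesterol biosynthesis (median 0.15, camera adjusted p = 0.00127, adjusted p = 0.640 with an estimated correlation) was lost without PBS_48h replicate 2 or EV_48h replicate 1 (largest adjusted p = 0.364), and oxidative phosphorylation (0.12, 0.0140, adjusted p = 0.671 with an estimated correlation) without PBS_48h replicate 2 (adjusted p = 0.144). Immediate early genes (median -0.24, camera adjusted p = 0.0329, adjusted p = 0.550 with an estimated correlation) were lost without PBS_48h replicate 1 or EV_48h replicate 1 (largest adjusted p = 0.208). Inflammatory cytokines (median -0.10, camera adjusted p = 0.0329, adjusted p = 0.181 with an estimated correlation) were lost without PBS_48h replicate 1 or EV_48h replicate 2 (largest adjusted p = 0.285), and osteoclast fusion genes (median -0.17, camera adjusted p = 0.0387, adjusted p = 0.550 with an estimated correlation) without PBS_48h replicate 2 or EV_48h replicate 1 (largest adjusted p = 0.309). Lipid efflux (camera adjusted p = 0.194), cell cycle (0.227), glycolysis (0.264), RANK signalling (0.432), TGF-beta (0.647) and the unfolded protein response (0.992) did not pass. The unfolded protein list had a median of 0.06, a mean of -0.00 and a test pointing up.

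Altogether 134 genes were called with vesicles at 48 h, 63 higher and 71 lower, with 28 up and 26 down at least 2-fold. The count was 34 without EV_48h replicate 1, 50 without EV_48h replicate 2, 59 without PBS_48h replicate 1 and 35 without PBS_48h replicate 2. In these fits 9 of the 16 named genes of largest change kept their calls, the 8 that rose and Pram1. Igf1 and Filip1l were lost without PBS_48h replicate 2 or EV_48h replicate 1, while Irf7, Slc7a8, Anxa3, Aif1 and Tmem176b were lost without 3 or 4 of the libraries. Myc, Msr1, Nqo1 and the named interferon-stimulated genes were each lost without at least PBS_48h replicate 2 or EV_48h replicate 1.

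**Figure D2:**
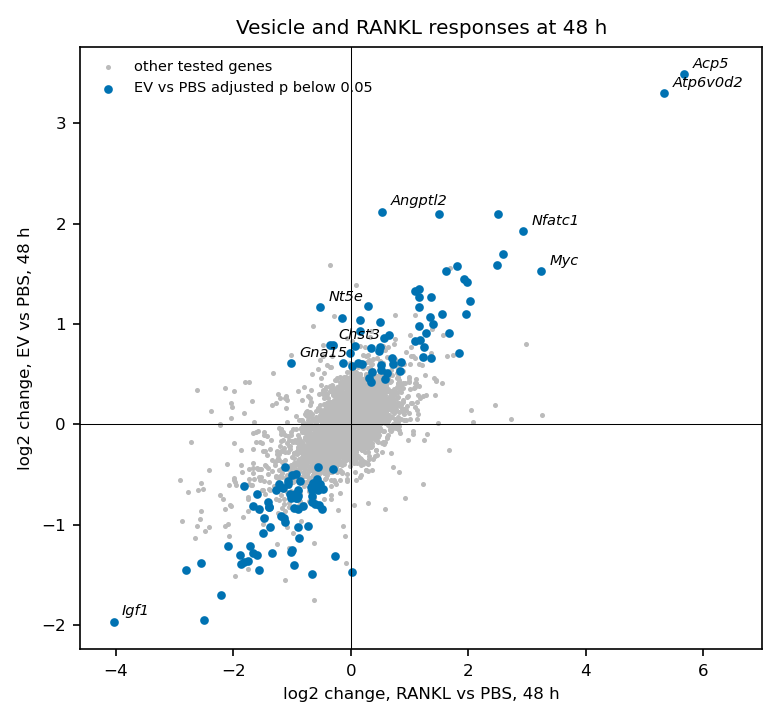
Each point is 1 of 10365 tested genes, with the log2 change of RANKL against PBS on the horizontal axis and of vesicles against PBS on the vertical axis, both at 48 h; blue points are the 134 genes called with vesicles. Acp5 and Atp6v0d2 rose most in both, while Angptl2 rose by 2.12 with vesicles and by 0.54 with RANKL.

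The vesicle and RANKL responses at 48 h were compared gene by gene. Of the 134 genes called with vesicles, 126 (94.0%) had the same sign with RANKL, 48 rose and 66 fell in both comparisons, and 1 was called in opposite directions. Independent lists would share 4.08 higher and 5.88 lower genes. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.637 and Spearman's rho = 0.520. Unchanged groups simulated against the same PBS libraries gave r = 0.50 in 100 draws. The covariance was 0.0579 against a simulated 0.0103, a difference of 0.0476. At 72 h, where EV against PBS lies across the library division, r was 0.497, no higher than the simulated 0.50. The covariance there was 0.0691 against 0.0103. At that time 372 genes rose and 194 fell in both (105 and 74.1 for independent lists), and 23 were called in opposite directions. With vesicles held against PBS_48h replicate 1 and RANKL against replicate 2, which share no library, r was 0.537, 18 genes rose and 8 fell in both (0.732 and 0.444 for independent lists), and 30 of 35 vesicle calls had the same sign with RANKL. With the PBS libraries exchanged r was 0.508, 17 rose and 18 fell in both (0.635 and 1.51), and 56 of 59 had the same sign.

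Adding vesicles to RANKL for 48 h raised Angptl2 further, from 1.64 ± 0.149 to 7.25 ± 0.0475 RPKM (1.65 ± 0.13, limma adjusted p = 1.6e-04). The creatine transporter Slc6a8 rose from 3.28 ± 0.739 to 11.2 ± 2.63 RPKM. The TGF-beta-binding surface protein Cd109 rose by 1.35 ± 0.16, Bcar3 by 1.31 ± 0.24, the galactosyltransferase B4galt1 by 1.28 ± 0.15, the urokinase gene Plau by 1.22 ± 0.23, the receptor Tgfbr1 by 1.11 ± 0.19 and Fosl2 by 1.01 ± 0.17. Pmaip1, a pro-apoptotic member of the BCL2 family, fell from 31.9 ± 1.36 to 12.6 ± 0.0891 RPKM (-1.27 ± 0.15, adjusted p = 0.00328). Gda (-1.23), Themis2 (-1.04), Cd300ld (-0.89), Bcl2a1d (-0.86), Cass4 (-0.79), Ugt1a7c (-0.78) and Naaa (-0.64) also fell. Acp5 (1.10), Atp6v0d2 (1.19), Ctsk (1.37), Nfatc1 (0.56), Dcstamp (0.44), Ocstamp (0.29), Oscar (0.51), Mmp9 (-0.34) and Irf8 (0.00) did not pass.

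In this comparison no list passed with an estimated correlation, and the list calls rest on a preset one. Interferon-stimulated genes were lower with 0 of 22 past the threshold over all genes (7 lower adjusted over the list alone, median -0.31, camera adjusted p = 1.6e-13, adjusted p = 0.209 with an estimated correlation). Resorption machinery was higher with 0 of 18 past (4 higher adjusted over the list alone, median 0.36, camera adjusted p = 4.8e-07, adjusted p = 0.327 with an estimated correlation). Osteoclast transcription factors rose in 2 of 18, Jdp2 at 0.98 and Fosl2 (5 adjusted over the list alone, camera adjusted p = 4.2e-05, adjusted p = 0.164 with an estimated correlation). TGF-beta and BMP targets rose in 1 of 8, Tgfbr1 (2 adjusted over the list alone, camera adjusted p = 0.0120, adjusted p = 0.164 with an estimated correlation). With 0 single members past, camera placed negative regulators of osteoclastogenesis (median -0.21, 0 adjusted over the list alone, adjusted p = 2.2e-05, adjusted p = 0.164 with an estimated correlation) and macrophage identity (-0.19, 5 lower adjusted over the list alone, adjusted p = 1.3e-04, adjusted p = 0.251 with an estimated correlation) lower. Cholesterol biosynthesis (median 0.17, adjusted p = 1.5e-04, adjusted p = 0.680 with an estimated correlation) and oxidative phosphorylation (0.13, adjusted p = 3.1e-04, adjusted p = 0.680 with an estimated correlation) were higher. Antigen presentation (median -0.13, camera adjusted p = 0.00731, adjusted p = 0.209 with an estimated correlation) and glycolysis (0.14, camera adjusted p = 0.0314, adjusted p = 0.876 with an estimated correlation) passed but were lost without RANKL_48h replicate 1 or EVRANKL_48h replicate 2, with largest adjusted p of 0.126 and 0.747. Cell cycle (camera adjusted p = 0.0993), NRF2 (0.330), lysosome (0.484), unfolded protein (0.486), fusion (0.633), inflammatory, immediate early, RANK signalling and LXR lists (each 0.986) did not pass. Signs differed for RANK signalling (median -0.02, mean 0.03, test down) and immediate early genes (0.03, 0.00, down).

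Limma called 45 genes in EV+RANKL against RANKL at 48 h, 28 higher and 17 lower, with 12 up and 3 down at least 2-fold. The count was 2 without EVRANKL_48h replicate 1, 8 without EVRANKL_48h replicate 2, 6 without RANKL_48h replicate 1 and 11 without RANKL_48h replicate 2. Of the 16 named genes of largest change, 1 kept its call in all 4 fits, Angptl2, while Cd109 and B4galt1 were lost only without EVRANKL_48h replicate 1.

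The vesicle effect was then followed with and without RANKL, in comparisons that share no library. At 48 h, 14 genes rose and 2 fell in both, where independent lists would share 0.170 and 0.116, and 121 of the 134 genes called with vesicles alone had the same sign on top of RANKL (r = 0.565 across genes). Genes that RANKL raised at least 2-fold at 72 h (137 genes) were higher with vesicles on top of RANKL at 48 h, with a median of 0.46 and 86.1% above 0 (camera p = 3.6e-34, p = 0.0383 with an estimated correlation). With vesicles alone at 48 h their median was 0.38, 89.8% were above 0 and 30 rose while 1 fell (camera p = 1.5e-26, p = 0.0623 with an estimated correlation). The 155 genes that RANKL lowered at 72 h had a median of -0.43 with vesicles alone at 48 h (14 lower and 1 higher, camera p = 1.7e-23, p = 0.0672 with an estimated correlation). On top of RANKL their median was -0.11 (camera p = 6.3e-04, p = 0.490 with an estimated correlation), and this call was lost without RANKL_48h replicate 1 (p = 0.168) or PBS_72h replicate 2 (p = 0.0556).

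**Figure D3:**
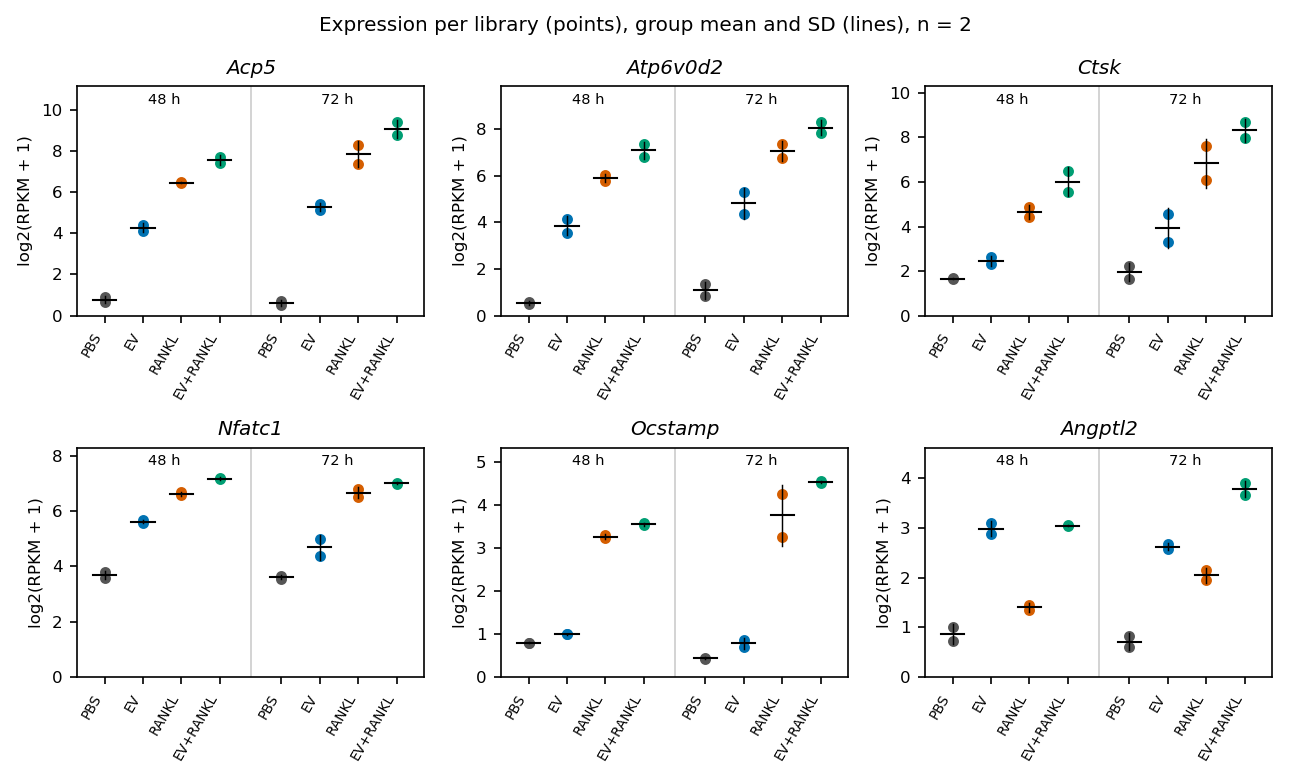
Points are the log2(RPKM + 1) values of single libraries, horizontal lines the mean and vertical lines the SD of 2 libraries, for 6 genes at 48 h and 72 h. Acp5, Atp6v0d2 and Nfatc1 lie higher with vesicles than with PBS at both times, Ocstamp does not pass the test with vesicles alone, and Angptl2 lies higher with vesicles whether or not RANKL is present.

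RANKL for 72 h raised most of the listed resorption genes over PBS. Acp5 was at 238 ± 101 RPKM against 0.539 ± 0.144 in PBS (7.21 ± 0.26, limma adjusted p = 1.1e-08). Atp6v0d2 rose by 5.96 ± 0.32, Ctsk by 4.90 ± 0.49, Mmp9 by 3.40 ± 0.36, Ocstamp by 3.32 ± 0.21, the chemokine receptor Ccr1 by 3.25 ± 0.32, Gstt1 by 3.20 ± 0.37 and Fosl2 by 3.07 ± 0.17. Nfatc1 (3.04), Oscar (2.63), Dcstamp (1.54), Itgb3 (0.83) and Fos (0.74) rose as well, with Dcstamp lost without PBS_72h replicate 1 and Itgb3 without RANKL_72h replicate 2. Igf1 (-3.11), Atf3 (-2.52), Basp1 (-2.48), Gpr84 (-2.46), Bhlhe41 (-2.37), Dab2 (-2.22), Cd14 (-2.14) and Plk2 (-2.13) fell. Bcl6 (-0.73), Cd81 (-0.41) and Irf8 (-1.64) fell too, Bcl6 and Cd81 with calls lost without RANKL_72h replicate 2 and that of Cd81 also without PBS_72h replicate 1, while Tnfrsf11a (0.47), Cd9 (0.26) and Cd63 (0.24) did not pass. The RANKL libraries of 72 h lie on both sides of the division of 5 and 11 libraries, with Acp5 at 166 and 309 RPKM.

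With RANKL at 72 h, 13 of 18 genes of the resorption machinery rose (15 adjusted over the list alone, median 0.89, camera adjusted p = 1.4e-11, adjusted p = 0.244 with an estimated correlation), and 11 of 18 osteoclast transcription factors rose while 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 5.1e-06, adjusted p = 0.113 with an estimated correlation), Prdm1 at 2.08 among them. Glycolysis and hypoxia response fell in 15 of 22 members (18 adjusted over the list alone, median -0.69, camera adjusted p = 1.6e-10, adjusted p = 0.263 with an estimated correlation). Pgk1 (-0.77), Pkm (-0.66) and the lactate exporter Slc16a3 (-1.01) fell. The unfolded protein and integrated stress response fell in 14 of 20 (17 adjusted over the list alone, camera adjusted p = 9.3e-08, adjusted p = 0.113 with an estimated correlation), with Creld2 at -0.73. Interferon-stimulated genes fell in 14 of 22 (18 adjusted over the list alone, camera adjusted p = 5.3e-08, adjusted p = 0.283 with an estimated correlation), such as Bst2 (-0.65). Oxidative phosphorylation rose in 4 of 22 (9 adjusted over the list alone, camera adjusted p = 4.4e-05, adjusted p = 0.464 with an estimated correlation). Its median was 0.30, and 0.11 with a term for the library division. Macrophage identity fell in 7 of 15 and rose in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 8.8e-04, adjusted p = 0.283 with an estimated correlation). Fcgr1 fell (-2.05). Inflammatory cytokines and NF-kB targets fell in 7 of 18 and rose in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00127, adjusted p = 0.113 with an estimated correlation). Ptgs2 (-1.42) and Tnf (-1.27) fell. RANKL_72h replicate 2 stood with the 5 libraries apart and replicate 1 with the others in all of these groups.

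Among the remaining lists of RANKL against PBS at 72 h, 4 passed camera and each was lost without at least 1 library, with 1 RANKL library on either side of the library division. These were cholesterol biosynthesis (median -0.24, camera adjusted p = 0.00689, 0.126 without PBS_72h replicate 2 or RANKL_72h replicate 1 at most), NRF2 targets (-0.20, 0.00914, 0.0550 without PBS_72h replicate 2), antigen presentation (-0.26, 0.0317, at most 0.106 without PBS_72h replicate 2 or RANKL_72h replicate 1) and negative regulators (-0.33, 0.0456, at most 0.132 without PBS_72h replicate 1 or RANKL_72h replicate 2). With an estimated correlation their adjusted p = 0.602, 0.263, 0.263 and 0.406. With a term for the division, the first 3 passed (medians -0.30, -0.25 and -0.28, adjusted p = 0.00507, 0.00835 and 0.00685) and negative regulators did not (-0.24, adjusted p = 0.132). Immediate early genes (camera adjusted p = 0.0517), cell cycle (0.110), RANK signalling (0.170), fusion (0.365), lysosome (0.686), LXR and TGF-beta (each 0.749) did not pass. Signs differed for lysosome genes (median 0.01, mean -0.04, test down) and TGF-beta (-0.01, 0.01, down).

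In the fit of all libraries limma called 1954 genes with RANKL at 72 h, 1008 higher and 946 lower, with 137 up and 155 down at least 2-fold. Far fewer were called with only the libraries of these groups, as given below. The SD of replicate differences was 0.24 in PBS and 0.31 in RANKL at 72 h, against 0.16 and 0.18 at 48 h. Adjusted p-values from the shared spread may thus be too small here. The count was 1194 without PBS_72h replicate 1, 1115 without PBS_72h replicate 2, 2854 without RANKL_72h replicate 1 and 738 without RANKL_72h replicate 2, and a term for the library division also gave 738. Of the 16 named genes of largest change 15 kept their calls in all 4 fits, and Atf3 was lost without RANKL_72h replicate 2. From 48 h to 72 h, 385 genes rose and 521 fell in both RANKL comparisons, where independent lists would share 65.3 and 78.4.

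Vesicles alone for 72 h again raised Acp5, to 37.7 ± 5.31 RPKM from 0.539 ± 0.144 (4.65 ± 0.26, limma adjusted p = 2.4e-06), Atp6v0d2 (3.73 ± 0.32), Angptl2 (1.91 ± 0.13) and Fosl2 (1.67 ± 0.17). The enolase Eno2 (1.89), Selenbp1 (1.84), the sialic acid receptor Cd33 (1.67) and Nfatc1 (1.07) rose, and Ctsk from 2.94 ± 1.09 to 15.9 ± 9.96 RPKM. Igf1 (-1.43), Rtp4 (-1.39), Tomm6 (-1.23), Zfp36l1 (-1.14), Nabp2 (-1.09), Raet1d (-1.07), Lyar (-1.07) and Cd5l (-1.07) fell. Both EV libraries of 72 h belong to the 5 libraries apart and both PBS libraries to the others, so these changes cannot be told apart from that division by this comparison alone. With a term for the division, which rests on the difference between the RANKL libraries of 72 h, 5 genes were called, Acp5 (3.76), Angptl2 (1.71), Tnfsf13b (1.16), Ms4a6b (1.52) and Dcstamp (-1.69). These 5 genes are named because they are few, after their values were seen. Without the term Tnfsf13b was at 0.75, Ms4a6b at 0.93 and Dcstamp at -0.07. The fall of Dcstamp with the term thus comes mainly from the RANKL libraries of 72 h, at 4.73 and 16.6 RPKM. Ctsk (66.4 and 196 RPKM) and Acp5 (166 and 309 RPKM) were also higher in RANKL_72h replicate 2 than in replicate 1. The term lowers the vesicle changes of Ctsk and Acp5 by that difference. None of the 8 genes that fell passed with the term, where Tomm6 turned to 0.11, Rtp4 was at -0.13, Cd5l at -0.27, Nabp2 at -0.30, Igf1 and Lyar each at -0.38, Raet1d at -0.47 and Zfp36l1 at -0.71. Of those that rose, Eno2 (2.04), Selenbp1 (2.40), Cd33 (2.34), Nfatc1 (0.79) and Ctsk (0.45) did not pass with it either (adjusted p from 0.439 to 0.810).

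In EV against PBS at 72 h, interferon-stimulated genes fell in 5 of 22 members (7 adjusted over the list alone, median -0.42, camera adjusted p = 1.9e-05, adjusted p = 0.870 with an estimated correlation), Ifi44 at -0.91 among them. Resorption machinery rose in 5 of 18 (6 adjusted over the list alone, median 0.45, camera adjusted p = 0.00231, adjusted p = 0.870 with an estimated correlation), with the proton pump subunit Tcirg1 at 0.90. Both groups lie across the library division, and with its term the medians were -0.28 (adjusted p = 0.0560) and -0.18 (adjusted p = 0.730). The term takes off the difference between the RANKL libraries of 72 h, so the shift from 0.45 to -0.18 comes from that pair. In it Ctsk, for example, was at 66.4 RPKM in replicate 1 and 196 in replicate 2. The value of -0.18 is therefore no measure of vesicles alone. Cholesterol biosynthesis (3 of 22 lower, 3 adjusted over the list alone, camera adjusted p = 0.00231) and cell cycle (2 of 27 lower, 2 adjusted over the list alone, camera adjusted p = 0.00280) fell, and both were lost without EV_72h replicate 1 (adjusted p = 0.608). Glycolysis and hypoxia response rose in 1 of 22 (0 adjusted over the list alone, camera adjusted p = 0.0342) and was lost without PBS_72h replicate 2 or EV_72h replicate 1 (at most 0.725), where the first of these fits left a median of 0.03 and a test pointing down. These 3 lists had adjusted p = 0.870 with an estimated correlation and lie across the same division. With its term cholesterol biosynthesis (-0.34, adjusted p = 0.00141) and glycolysis (0.28, adjusted p = 2.4e-04) passed, and cell cycle did not (-0.21, adjusted p = 0.0560).

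The other lists of this comparison did not pass camera, with the same library division across them. They were immediate early genes (adjusted p = 0.0728), lysosome (0.0739), osteoclast transcription factors (0.158), fusion and NRF2 (each 0.266), inflammatory cytokines (0.348), oxidative phosphorylation (0.401), LXR (0.503), macrophage identity (0.603), unfolded protein (0.698), RANK signalling and negative regulators (each 0.744), TGF-beta and antigen presentation (each 0.996). With the term for the division 2 of them passed, macrophage identity at a median of 0.40 (adjusted p = 2.4e-04) and oxidative phosphorylation, which turned from 0.13 to -0.25 (adjusted p = 9.4e-05). Both of these p-values rest on the preset correlation and on a term set by 1 pair of RANKL libraries. The median, mean and test differed in sign for the unfolded protein list (median 0.15, mean 0.10, test down), negative regulators (-0.05, 0.07, up) and TGF-beta (0.03, 0.17, down).

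In the fit of all libraries 1895 genes were called between vesicles and PBS at 72 h, 1083 higher and 812 lower, with 86 up and 15 down at least 2-fold. Far fewer were called with only the libraries of these groups, as given below. The SD of replicate differences was 0.24 in PBS and 0.29 in EV at 72 h, against 0.16 in each at 48 h. Adjusted p-values from the shared spread may thus be too small here. The count was 55 without EV_72h replicate 1, 2918 without EV_72h replicate 2, 36 without PBS_72h replicate 2 and 1720 without PBS_72h replicate 1. Of the 16 named genes of largest change 4 kept their calls in these fits, Acp5, Atp6v0d2, Angptl2 and Fosl2. Atp6v0d2 (3.13, adjusted p = 0.107) and Fosl2 (0.99, adjusted p = 0.149) no longer passed with the term for the division. Zfp36l1 was lost without PBS_72h replicate 1, Raet1d and Nfatc1 without PBS_72h replicate 2, and the others without at least PBS_72h replicate 2 and EV_72h replicate 1. Of the 134 genes called at 48 h, 119 had the same sign at 72 h and 65 were called again in that direction. With the term for the division 106 had the same sign and 2 were called. The sets of genes that RANKL changed at 48 h had medians of 0.55 for the 82 that rose (camera p = 1.2e-13, p = 0.0803 with an estimated correlation) and -0.11 for the 227 that fell (p = 0.0107, p = 0.618 with an estimated correlation). The lower set turned to 0.32 with the term for the division and to 0.07 without EV_72h replicate 2, and its call was lost without PBS_72h replicate 1 (-0.08).

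Adding vesicles to RANKL for 72 h raised Rab15, a GTPase of membrane traffic, from 1.95 ± 0.536 to 9.60 ± 1.61 RPKM (1.85 ± 0.15, limma adjusted p = 1.4e-04), and Angptl2 from 3.13 ± 0.408 to 12.8 ± 1.57 RPKM (1.74 ± 0.13, adjusted p = 8.0e-05). The sodium-proton exchanger Slc9b2 rose by 1.62 ± 0.27, Csf2rb2 by 1.36 ± 0.21, Rufy4 by 1.33 ± 0.22, Slc6a8 by 1.32 ± 0.26, Slc37a2 by 1.29 ± 0.29 and Acp5 by 1.24 ± 0.26. Rtp4 fell most (-2.34 ± 0.37), followed by Irf7 (-1.44), the oxidase subunit Cybb (-1.40), Lgals9 (-1.34), Ifi44 (-1.32), Cd300ld (-1.12 ± 0.12, adjusted p = 0.00150), Oas2 (-1.07) and Ezr (-1.06). Both EV+RANKL libraries and RANKL replicate 2 are among the 5 libraries apart, and RANKL replicate 1 is not. With RANKL replicate 1 left out, which equals a term for the division, Rab15 (1.66), Angptl2 (1.64) and Cd300ld (-0.99) kept their calls among the named genes.

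Resorption machinery rose in 4 of 18 members with vesicles on top of RANKL at 72 h (15 adjusted over the list alone, median 0.66, camera adjusted p = 6.8e-12, adjusted p = 0.382 with an estimated correlation), Slc9b2, Itgav (1.10), Acp5 and Slc4a2 (0.79). Interferon-stimulated genes fell in 6 of 22 (12 adjusted over the list alone, median -0.47, camera adjusted p = 6.4e-11, adjusted p = 0.382 with an estimated correlation), among them Dhx58 (-0.83) and Xaf1 (-0.64). Cell cycle fell in 1 of 27, Birc5 at -0.60 (5 adjusted over the list alone, camera adjusted p = 4.3e-07, adjusted p = 0.460 with an estimated correlation). Fusion genes rose in 1 of 15, Cd109 at 1.29 (5 adjusted over the list alone, camera adjusted p = 4.3e-04, adjusted p = 0.382 with an estimated correlation), and transcription factors in 1 of 18, Fosl2 at 0.80 (3 adjusted over the list alone, camera adjusted p = 0.00600, adjusted p = 0.382 with an estimated correlation). With 0 members past the threshold over all genes, glycolysis (median 0.40, 4 higher adjusted over the list alone, camera adjusted p = 4.5e-08, adjusted p = 0.417 with an estimated correlation) and lysosome genes (0.34, 9 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.3e-05, adjusted p = 0.460 with an estimated correlation) were higher. With the term for the library division, which lies across the RANKL pair, the medians were 0.48 for resorption, -0.37 for interferon-stimulated genes, -0.34 for cell cycle, 0.39 for glycolysis and 0.26 for lysosome, and each list passed camera.

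In the same comparison 3 lists passed camera and were lost without a library. These were oxidative phosphorylation (median 0.16, camera adjusted p = 7.2e-04, 0.945 without RANKL_72h replicate 1), cholesterol biosynthesis (0.13, 0.0135, 0.126 without RANKL_72h replicate 2) and macrophage identity (-0.25, 0.0268, at most 0.632 without RANKL_72h replicate 1 or EVRANKL_72h replicate 2). With an estimated correlation their adjusted p = 0.601, 0.666 and 0.511. With the term for the library division the medians were -0.02 (adjusted p = 0.945), 0.08 (adjusted p = 0.00775) and -0.17 (adjusted p = 0.563). TGF-beta (camera adjusted p = 0.0561), inflammatory cytokines (0.196), unfolded protein and LXR (each 0.237), negative regulators (0.324), RANK signalling and immediate early genes (each 0.557), NRF2 (0.598) and antigen presentation (0.696) did not pass. Of these, TGF-beta (0.20, adjusted p = 0.00506), inflammatory cytokines (0.20, adjusted p = 0.00603) and immediate early genes (0.14, adjusted p = 0.00775) passed with the term. Signs differed for antigen presentation (median 0.03, mean -0.05, test down) and immediate early genes (-0.02, 0.04, up).

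In the fit of all libraries limma called 190 genes in EV+RANKL against RANKL at 72 h, 135 higher and 55 lower, with 31 up and 11 down at least 2-fold. Far fewer were called with only the libraries of these groups, as given below. The SD of replicate differences was 0.31 in RANKL and 0.19 in EV+RANKL at 72 h, against 0.18 and 0.17 at 48 h. Adjusted p-values from the shared spread may thus be too small here. The count was 5 without EVRANKL_72h replicate 1, 50 without EVRANKL_72h replicate 2, 9 without RANKL_72h replicate 1 and 1815 without RANKL_72h replicate 2. Rab15, Angptl2 and Cd300ld kept their calls in all 4 fits, and each of the other named genes and list members was lost at least without RANKL_72h replicate 1 or EVRANKL_72h replicate 1. All 45 genes called at 48 h had the same sign at 72 h, 19 rose and 7 fell in both, and r across genes was 0.602. With the term for the division, which equals leaving out RANKL_72h replicate 1, 44 had the same sign, 4 of the 45 were called and r was 0.537. The 82 genes that RANKL raised at 48 h had a median of 0.42 (camera p = 5.6e-14, p = 0.0769 with an estimated correlation). The 227 that it lowered had a median of -0.19 (p = 4.0e-04, p = 0.493 with an estimated correlation), which turned to 0.03 without RANKL_72h replicate 1 and was lost without EVRANKL_72h replicate 2 (-0.08).

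**Figure D4:**
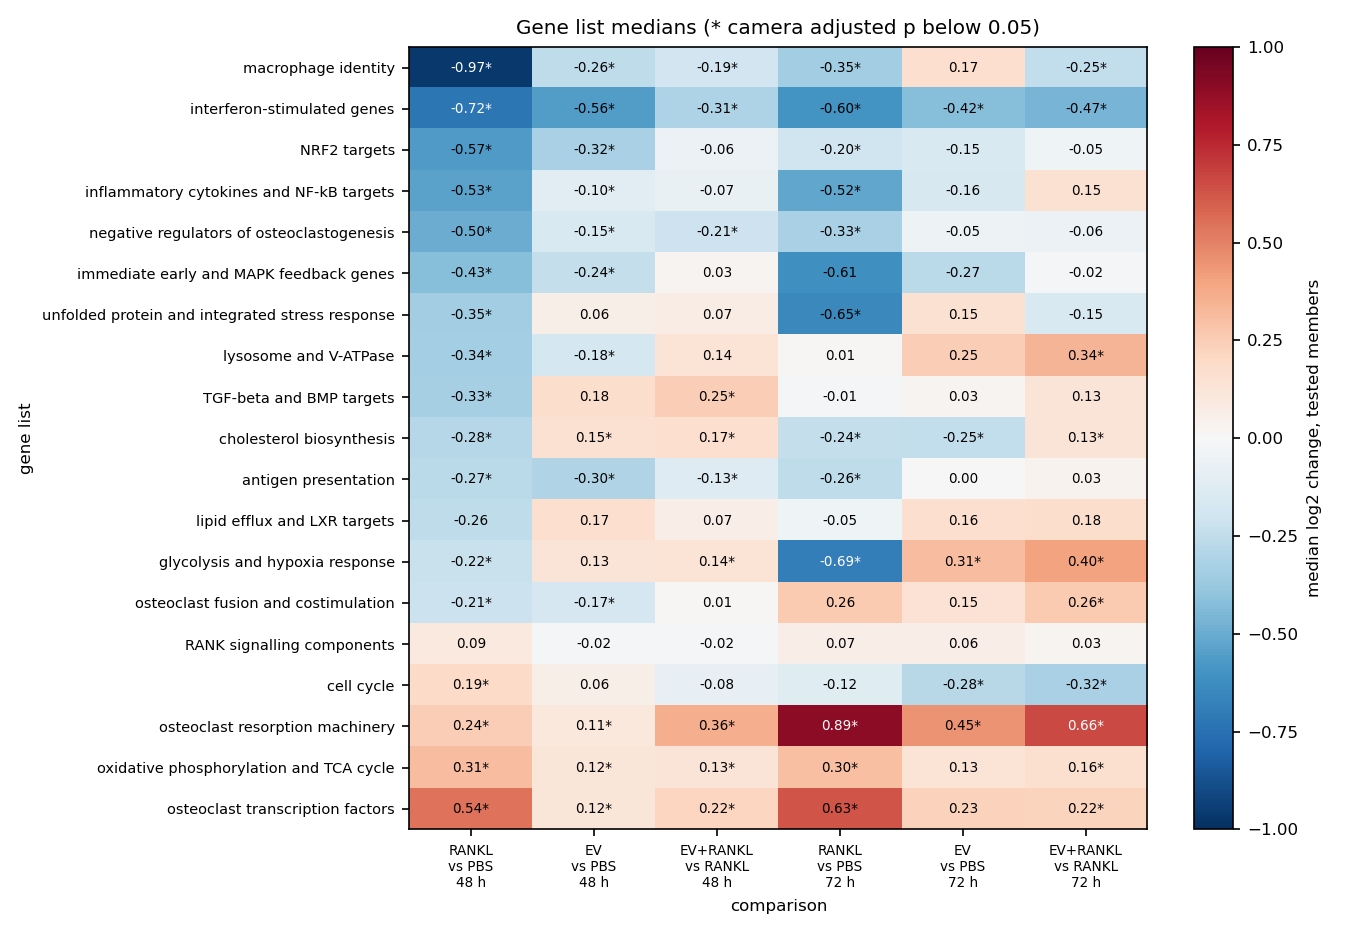
Each cell gives the median log2 change of the tested members of 1 of 19 gene lists in 1 of 6 comparisons, with an asterisk where the camera adjusted p is below 0.05. Interferon-stimulated genes lie below 0 and resorption machinery above 0 in all 6 comparisons. With the term for the library division, resorption machinery was at -0.18 in EV against PBS at 72 h. That value carries the difference between the RANKL libraries of 72 h.

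Whether vesicles act differently with and without RANKL was tested as an interaction. At 48 h 1 gene passed, the collagenase gene Mmp8 (1.73 ± 0.16, limma adjusted p = 0.00115), and 318 had an unadjusted p below 0.05. The Mmp8 call was lost with a pseudocount of 0.1 (2.98 ± 0.61, adjusted p = 0.442). Acp5 (-2.39), the complement genes C1qa (1.42) and C1qb (1.40) and Rab15 (1.28) came next and did not pass. At 72 h 1 gene passed, Acp5 (-3.41 ± 0.36, adjusted p = 0.00524), and 959 had an unadjusted p below 0.05, with Rab15 (1.44), Atp2a3 (-1.29), Cd300ld (-1.11), Rnasek (0.79) and Atp6v0d2 (-2.72) next and not past. The Acp5 call was lost with a pseudocount of 5 (-1.72 ± 0.34, adjusted p = 0.144) and without EV_72h replicate 1 (-3.27, adjusted p = 0.0518). The Acp5 interaction is negative on the log2 scale, since its log2 change with vesicles was 4.65 without and 1.24 with RANKL. In RPKM, it was at 37.7 ± 5.31 with vesicles, at 166 and 309 with RANKL and at 663 and 435 with both. The 72 h count was 64 without RANKL_72h replicate 1, 21 without RANKL_72h replicate 2, 14 without EV_72h replicate 2, 3 without PBS_72h replicate 1, 2 without PBS_72h replicate 2 and 0 without EV_72h replicate 1, and the 48 h count 2 without PBS_48h replicate 2.

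Among interaction tests of lists, NRF2 targets (median 0.19, 0 of 17 past, camera adjusted p = 6.3e-06, adjusted p = 0.176 with an estimated correlation) and lysosome genes (0.21, 0 of 23 past, camera adjusted p = 4.4e-05, adjusted p = 0.585 with an estimated correlation) passed at 48 h in every fit without 1 library. At 72 h cholesterol biosynthesis did (median 0.42, 0 of 22 past, camera adjusted p = 3.4e-10, adjusted p = 0.595 with an estimated correlation), with 5 of the 8 libraries apart from the rest. At 48 h interferon-stimulated genes (camera adjusted p = 8.3e-04, at most 0.861 without PBS_48h replicate 2 or EV_48h replicate 1), fusion (0.00356, 0.0642 without EV_48h replicate 1), cell cycle (0.00694, 0.0511 without EVRANKL_48h replicate 1) and TGF-beta (0.0367, at most 0.498 without PBS_48h replicate 2, RANKL_48h replicate 1 or EV_48h replicate 1) passed but were lost. With an estimated correlation their adjusted p = 0.731, 0.448, 0.791 and 0.342. At 72 h macrophage identity (camera adjusted p = 0.00880) was lost without PBS_72h replicate 1, RANKL_72h replicate 1, EV_72h replicate 1 or EVRANKL_72h replicate 2 (at most 0.648). The inflammatory (0.0175), glycolysis (0.0316) and immediate early lists (0.00473) were lost without PBS_72h replicate 1, RANKL_72h replicate 2, EV_72h replicate 2 or EVRANKL_72h replicate 1 (at most 0.707, 0.763 and 0.537). With an estimated correlation the adjusted p of these 4 lists was 0.609, 0.541, 0.965 and 0.595. With the term for the division macrophage identity (-0.71, adjusted p = 1.4e-05) and cholesterol biosynthesis (0.49, adjusted p = 1.2e-07) passed at 72 h and the other 3 did not (adjusted p = 0.192 for inflammatory and immediate early lists, 0.228 for glycolysis). It made 6 further lists pass, resorption (0.49, adjusted p = 1.7e-04), fusion (0.11, adjusted p = 0.00234), oxidative phosphorylation (0.24, adjusted p = 2.1e-06), lysosome (0.22, adjusted p = 0.0342), interferon-stimulated genes (-0.17, adjusted p = 0.0361) and negative regulators (-0.06, adjusted p = 0.0449).

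In further interaction tests of lists, none past the threshold, median, mean and test differed in sign. At 48 h these were resorption (median 0.22, mean -0.03, test up), negative regulators (0.02, 0.01, down), RANK signalling (-0.03, 0.06, up), macrophage identity (0.06, -0.03, up), cholesterol (0.00, -0.02, up), glycolysis (-0.00, 0.04, up) and unfolded protein (-0.01, 0.06, up). At 72 h, with 5 of the 8 libraries apart from the rest, they were resorption (0.24, -0.09, up), transcription factors (0.02, -0.03, up), RANK signalling (-0.08, -0.02, up) and LXR (-0.10, -0.07, up). The resorption list had 1 of 18 members past at 72 h, Acp5, which was lower.

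Over time, PBS cultures changed in few genes, with Cxcl14 (-2.48 ± 0.34), Dmpk (-2.43), Cd207 (-2.05), Pram1 (-1.99) and Id2 (-1.93) lower and Fam13c (1.44), St3gal6 (1.29), Ak4 (1.29), Cst7 (1.28) and Gfod1 (0.88) higher at 72 h than at 48 h. Limma called 67 genes there, 81 with a term for the library division, 3 without PBS_48h replicate 2 or PBS_72h replicate 1, 41 without PBS_48h replicate 1 and 242 without PBS_72h replicate 2. With RANKL 625 genes were called, led by Ighm (2.56), Ctsk (2.20), Gpnmb (1.94), Cd33 (1.90) and Ms4a6c (1.70), while Tmem26 (-1.89), Myc (-1.68), Cxcl14 (-1.65) and Lamc1 (-1.59) fell. That count was 177 without RANKL_48h replicate 1, 0 without RANKL_48h replicate 2, 1739 without RANKL_72h replicate 1 and 57 without RANKL_72h replicate 2 or with the term, and 2957 genes had an unadjusted p below 0.05 with all libraries.

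With vesicles alone 3347 genes were called between the times, with Selenbp1 (3.51), Ndrg1 (3.07), Eno2 (3.05), Aldh1l2 (2.85) and Trib3 (2.83) higher and Olfml3 (-2.41), Pmepa1 (-2.39), Cxcl14 (-2.29), Dmpk (-2.08) and Cav1 (-1.85) lower at 72 h. With EV+RANKL 4027 were called (1802 higher and 2225 lower, and 2347 higher and 1855 lower under median-of-ratios scaling), among them Oscar (2.44), Ctsk (2.31), Eno2 (2.31), Eno3 (2.15), Cd83 (2.05), Myc (-1.80), Cxcl14 (-1.76), Tmem26 (-1.67) and Rbfox1 (-1.66). All 72 h libraries of both comparisons belong to the 5 apart, and with a term for the division 1 gene was called in each. The EV count was 1362 without EV_48h replicate 1, 1134 without EV_48h replicate 2 and 649 without EV_72h replicate 1. The EV+RANKL count was 1423 without EVRANKL_48h replicate 2 and 1428 without EVRANKL_72h replicate 1.

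Few differences between times in the treatment effects passed the threshold, which does not show that the effects were alike. For RANKL 3 genes passed, Mmp8 (1.72 ± 0.16), Sesn1 (1.27 ± 0.18) and Slc16a12 (0.98 ± 0.12), with 1202 at an unadjusted p below 0.05 and 318 called without RANKL_72h replicate 1, 2 without RANKL_72h replicate 2, 4 without PBS_48h replicate 1 and 1 without PBS_48h replicate 2, either RANKL_48h library or either PBS_72h library. In each of these fits Mmp8 kept its call, which was lost with a pseudocount of 0.1 (3.40 ± 0.61, adjusted p = 0.122). Sesn1 passed only without RANKL_72h replicate 1 (at most 0.340), and Slc16a12 only there and without PBS_48h replicate 1 (at most 0.185). For vesicles alone 2 passed, Mmp8 (1.29 ± 0.16) and a predicted gene, with 1493 called without EV_72h replicate 2, 4 without PBS_72h replicate 1, 1 without PBS_72h replicate 2 and 0 without either PBS_48h library, either EV_48h library or EV_72h replicate 1. With all libraries limma gave 2012 genes at an unadjusted p below 0.05. For vesicles on top of RANKL limma called 0, with 375 at an unadjusted p below 0.05 and 90 called without RANKL_72h replicate 2, and Tnfsf8 (1.02) and Ms4a6c (-1.21) were among the genes of smallest p.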

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

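All tests of explanations given here were chosen after the results they address were seen, while the tests of differences between conditions and times were planned.

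Mmp8 was singled out because its vesicle effect differed with and without RANKL at 48 h (1.73 ± 0.16, limma adjusted p = 0.00115) and because its RANKL and vesicle effects differed between times (1.72 and 1.29). It was at 3.66 and 3.88 RPKM in the PBS libraries of 48 h, at 0.470 and 0.457 with vesicles, and at 0.0438 and 0.0204 with RANKL. In PBS at 72 h it was at 0.511 and 0.780 RPKM, so each of these differences rests on the PBS level at 48 h and on values below 1 RPKM elsewhere. With a term for the library division the differences were 1.73, 1.77 and 1.40, the last no longer past (adjusted p = 0.335). With a pseudocount of 0.1 none passed (2.98, 3.40 and 1.65, SE 0.61, adjusted p = 0.442, 0.122 and 0.199), as the spread at low values grew. The last was also lost without any 1 of 5 of its libraries (at most 0.191).

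Acp5 was singled out because its vesicle effect at 72 h was smaller on the log2 scale with RANKL than without (-3.41 ± 0.36, limma adjusted p = 0.00524), and -2.96 with the library term (adjusted p = 0.00416). The call was lost with a pseudocount of 5 (-1.72 ± 0.34, adjusted p = 0.144), which shrinks changes from a PBS level below 1 RPKM, and without EV_72h replicate 1 (-3.27, adjusted p = 0.0518). Sesn1 (1.27) and Slc16a12 (0.98) differed between times in their RANKL effect, and with the library term their values were 1.09 and 0.89 (adjusted p = 0.0774 and 0.0517). Sesn1 was lost without 7 and Slc16a12 without 6 of 8 libraries (at most 0.340 and 0.185), and Sesn1 with a pseudocount of 0.1 (adjusted p = 0.0561) and with no filter (adjusted p = 0.0670).

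The division of 5 libraries of 72 h from the other 11 was weighed first. For 65 genes with a wide gap, chosen without the RANKL libraries of 72 h, replicate 1 lay at 0.20 and replicate 2 at 0.90. Treatment alone does not account for this difference of 0.699 between libraries of the same group. The division was drawn from these data with replicate 2 inside it, however. The test therefore cannot decide whether treatment set the vesicle libraries apart. For 2104 genes with a narrow gap the difference was 0.481, and treatment stays open for both gaps. A step that acts on short transcripts may contribute to the narrow gap, where genes higher in the 5 libraries had a median length of 3712 bases and genes lower 4513. The difference of -800.5 lies outside the -29.1 to 508 of matched random lists. Pooled over both directions, genes of the narrow gap had a median of 4172 bases, within the random 4119 to 4374. This pooled test came first and was replaced by the test per direction after its values were seen. For the wide gap a step on short transcripts stays open, since the difference of -416 bases lies within the random -1478 to 1588. Both directions were short there (1988 and 2404 bases, against random medians of 3682 and 3573). Vesicles given by mistake to RANKL_72h replicate 2 are argued against, since over 45 vesicle genes it lay at 0.306 of the way to EV+RANKL.

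The larger count between vesicles and PBS at 72 h than at 48 h in the fit of all libraries was weighed next. That fit shares 1 estimate of the spread. The SD of replicate differences was 0.163 in PBS and 0.159 in EV at 48 h, and 0.24 and 0.29 at 72 h. With only the libraries of the compared groups, more genes were called at 48 h than at 72 h, as given below. Unequal spread was not tested as an explanation. Of the 1895 calls, 86.2% had the same sign from RANKL_72h replicate 1 to replicate 2, against 64.1% of genes not called. Among the calls, 924 were genes without overlap between the library sets of the division, against 635 of the 8470 genes not called. The division was drawn with RANKL_72h replicate 2 on the vesicle side, so these genes have the same sign by construction. The percentages therefore cannot decide how much of the count the library division explains, and the division stays open as an explanation. A vesicle effect under way at 48 h stays open, with 68.0% of the calls of the same sign there against 54.3% of the others.

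Last, vesicle and RANKL changes ran together at 48 h. Error of single PBS libraries, shared by both comparisons, is argued against as the whole cause. With vesicles and RANKL each held against another PBS library, r was 0.537 and 0.508. The labels do not say that the PBS libraries came from separate cultures. A deviation common to both PBS libraries would remain in this test, so that part of a shared control stays open. Traces of RANKL in the vesicles are argued against only weakly as the whole cause by 17 genes called past the RANKL level in the same direction. The argument holds if genes respond in 1 direction as the dose grows. Both comparisons behind the 17 genes use the same EV libraries, and the number that shared error would give was not estimated. Such traces may still be part of the cause, and a RANKL-like action of the vesicles was not separated from them.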

How the results depend on the processing

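The settings with pseudocounts of 0.1 and 5, the library term, the 48 h libraries alone, and fits of lists and RANKL-responsive sets without 1 library were chosen after the data were seen. The count-based tests of the plan (DESeq2, edgeR) and scalings of counts were not run, because the values are not counts. Of the alternatives, 91 counts stayed within 1.5 times and 108 moved. For lists 1439 stayed the same, 216 were weaker, 91 stronger and 2 reversed, for RANKL-responsive sets 96, 12, 0 and 4, and for single genes 6575, 761, 259 and 3. Where no construction is named below, the cause was not tested.

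With the 48 h libraries alone, and so another estimate of the spread, counts were 3147 (RANKL), 506 (EV), 273 (EV+RANKL against RANKL) and 4 (interaction). With only the libraries of the compared groups they were 2596, 344 and 108 at 48 h, 412, 10 and 8 at 72 h, and 3 (PBS), 1072 (EV) and 0 (RANKL, limma) over time. With no filter, which adds genes of few reads, they were 69 and 1062 for EV at 48 h and 72 h, 13 and 39 for the interactions, 37 (PBS) and 164 (RANKL) over time, and 15, 14 and 22 for the time differences of RANKL, EV and EV+RANKL. The filter above 5 RPKM gave 0 for the 48 h interaction and 0 for the EV time difference, 1 for that of EV+RANKL, and -0.0943 for the lower RANKL set of 48 h in EV at 72 h. Mmp8, the named gene of that interaction and of the EV time difference, did not reach this filter and was not tested. Its loss there was fixed by the filter.

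The library term gave 234 and 115 for EV and EV+RANKL at 48 h, 738, 5 and 9 for RANKL, EV and EV+RANKL at 72 h, 2 and 20 for the interactions, 1 (EV), 57 (RANKL) and 1 (EV+RANKL) over time and 0 for the EV time difference. It reversed the lower RANKL set of 48 h in EV+RANKL (0.0326) and in EV (0.32) at 72 h, and Tomm6 (0.11), Glb1 (-0.00888) and B2m (0.0825) in EV at 72 h. Some list medians in EV at 72 h also changed sign with the term, among them resorption machinery (from 0.45 to -0.18) and oxidative phosphorylation (from 0.13 to -0.25). These shifts come from the difference between the RANKL libraries of 72 h, which the term takes off. A pseudocount of 0.1 ended each Mmp8 call, so that the 1 interaction gene of 48 h was another, and gave 124 for EV+RANKL at 72 h and 1 and 0 for the time differences of RANKL and EV. A pseudocount of 5 gave 4 and 3 for the interactions, the 3 without Acp5, and 1 for the EV+RANKL time difference. With an estimated correlation, RANKL-responsive sets no longer passed at medians of -0.11 (lower set of 72 h in EV+RANKL), 0.38 and -0.43 (in EV), 0.42 and -0.19 (sets of 48 h in EV+RANKL) and 0.55 and -0.11 (in EV).

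Replicate numbers do not pair the samples by the labels, the number of 1 EV+RANKL library of 48 h is inferred, and with 2 pairs the correlations of replicate differences were 0.165, 0.334, 0.476, -0.04, 0.460 and 0.0615. The replicate block gave 241 (EV), 112 (EV+RANKL) and 8 (interaction) at 48 h, 313 and 4 at 72 h, 179 (PBS) and 1302 (RANKL) over time, and 10 and 1 for the time differences of RANKL and EV+RANKL.

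Without 1 library, which leaves a group with 1 sample assumed to vary like the others, counts ranged from 717 to 908 (RANKL), 34 to 59 (EV), 2 to 11 (EV+RANKL) and 1 to 2 (interaction) at 48 h, and from 738 to 2854, 36 to 2918, 5 to 1815 and 0 to 64 at 72 h. Over time they ranged from 3 to 242 (PBS), 649 to 4113 (EV), 0 to 1739 (RANKL) and 1423 to 3231 (EV+RANKL), and for the time differences from 1 to 318, 0 to 1493 and 0 to 90. The higher RANKL sets ranged from 0.27 to 0.54 and 0.21 to 0.47 (EV+RANKL and EV at 48 h) and from 0.19 to 0.64 and 0.37 to 0.60 at 72 h. The lower sets ranged from -0.19 to -0.0264 and -0.51 to -0.27 at 48 h, and from -0.41 to 0.0326 and -0.26 to 0.0711 at 72 h, reversed without RANKL_72h replicate 1 and without EV_72h replicate 2. The glycolysis list reversed without PBS_72h replicate 2 in EV (0.0349, with a range up to 0.496) and without PBS_72h replicate 1 in the interaction (-0.10, with a range up to 0.356) at 72 h. Depth limits genes below about 1 RPKM, which rest on few reads.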

Other observations

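The comparison of vesicles with RANKL at 48 h, and the choice of genes below, were made after the results were seen.

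Vesicles and RANKL were set against each other directly at 48 h, where 460 genes were higher and 260 lower with vesicles. Among them were 17 genes called with vesicles against PBS in the same direction, 15 higher and 2 lower. Gna15, a G protein subunit, was 1.62 ± 0.13 higher with vesicles than with RANKL, since it rose by 0.61 with vesicles and had a change of -1.01 with RANKL. Angptl2 (1.59 ± 0.13), the sulfotransferase Chst3 (1.14), Nt5e, the ectonucleotidase CD73 (1.69), Odf3l1 (1.21), B4galt1 (0.88) and Mical2 (0.56) were higher, and Filip1l (-1.50) and the sialyltransferase St3gal5 (-1.03) lower.

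Of the genes called in both vesicle comparisons of 48 h, Cyp2s1 rose by 1.02 alone and 1.29 with RANKL, Pxdn by 0.73 and 0.77, Rilpl1 by 1.07 and 0.83, and Rai14 by 1.53 and 0.74. Susd6 fell in both (-0.77 and -0.53).

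The complement genes C1qa, C1qb and C1qc fell with vesicles at 48 h (-1.46, -1.40 and -0.69) and with RANKL (-1.55, -1.88 and -1.03), and C1qb had a change of 0.00 when vesicles were added to RANKL. The BMP target genes Id1 (-1.23), Id2 (-1.38) and Id3 (-1.75) and the TGF-beta target Pmepa1 (1.59) did not pass with vesicles at 48 h.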
